A study of Rattus norvegicus with 20 samples.

How the data were processed

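Liver RNA of male Sprague-Dawley rats was measured on Affymetrix expression arrays, 1 array per rat. Rats were 4 weeks old on arrival and were acclimatised for 7 d. They were then placed in 4 groups of 7 rats and fed a lignan-free diet or a diet with 0.2% sesamin, episesamin or sesamolin for 15 d. Arrays came from 5 rats per group, since the rats with the highest and the lowest body weight of each group were left out, and replicate arrays were not pooled. Biotin-labelled cRNA was prepared from total RNA. The values deposited by the authors are in the unit intensity, 1 linear value per probe set and array for 31099 probe sets on 20 arrays. Raw values ran from 0.0222 to 18018.4 and array means from 159 to 271, a 1.7-fold range, so no common scale had been set between arrays. The software that computed these values is not given in the sources used here.

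Arrays were quantile normalized, an offset of 5.85 (the 20th percentile of the normalized values) was added, and log2 was taken. Of the probe sets, 20832 had 1 gene symbol, 436 had several and 9831 were not listed in the annotation, and only the first class was used. Control probe sets (57, of which 6 had 1 symbol and 51 were not listed) were left out, which leaves 20826 probe sets for 14217 genes. Probe sets had to exceed 17.8, the 40th percentile, on at least 5 arrays. The probe set with the highest mean stood for its gene, which gave 11576 genes, 107 of them on probe sets whose suffix marks possible cross-hybridization. Correlations between arrays of a diet ranged from 0.9596 to 0.9798 and no 2 columns were identical. Quantile normalization was chosen once the table was seen to be unscaled and before any test was run. The design text written earlier named no normalization between arrays, and that form was run as an added alternative.

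A linear model with 4 group means was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (16 residual and 2.596 prior degrees of freedom). The 6 comparisons were each lignan against the lignan-free diet and each pair of lignans. Moderated t tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and genes with an adjusted p below 0.05 are called. Intervals cover 95%. An F test over the 4 diets called 566 genes, and the first and second principal components held 15.8% and 9.26% of the variance.

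The comparisons, gene lists, naming rule and first set of alternatives were written before the data were examined. The 30 lists cover peroxisomal, mitochondrial and microsomal omega-oxidation of fatty acids, peroxisome biogenesis, fatty acid uptake and hydrolysis, ketone body synthesis, fatty acid, cholesterol and bile acid synthesis, lipoproteins, CAR and PXR, AhR and Nrf2 targets, conjugating enzymes, sex-dependent genes, glycolysis, amino acid breakdown, oxidative phosphorylation, endoplasmic reticulum stress, acute phase, cell cycle, interferon, circadian clock, and markers of Kupffer cells, lymphocytes and neutrophils, stellate cells, endothelium, bile duct, red blood cells, and adipocytes and exocrine pancreas. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry, and p-values were adjusted over the lists. The ketone body synthesis list also holds Pdk4, Angptl4, Fgf21, Slc16a1 and Slc16a6. A list's score on an array is the mean of its genes relative to the lignan-free mean. Single values were compared by two-sided exact permutation, whose smallest p for 5 against 5 arrays is 0.00794.

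Named genes follow a rule. Against the lignan-free diet, these are the 12 largest increases and 8 largest decreases among called genes whose 5 lignan arrays all lie on one side of the 5 lignan-free arrays. For each pair of lignans they are the 6 largest in either direction, and from each list up to 4 members with the lowest adjusted p and up to 2 with the highest level that did not pass. Symbols of uncharacterised loci were passed over. A gene outside the rule is marked where it is named. Where a group's mean or most of its arrays lie below the filter level, the fold is also given as a bound: the brighter group's mean log2 intensity against the dimmer group's, with each array of the latter at the filter level or its own value, whichever is higher.

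Alternatives were median scaling of the arrays, an offset of 16, no offset, no filter, a filter at the 60th percentile (45.1), the mean of a gene's probe sets, every probe set on its own, trended and robust eBayes, array weights, only the groups compared in the fit, the replicate number as a block, the list tests named above, and leaving out each array in turn. After the data were seen, 5 more were added: no normalization between arrays, array brightness as a covariate, the actin 3' to 5' ratio as a covariate, leaving out the 6 arrays of mean raw intensity below 200, and leaving out the 4 arrays numbered 1. The fit was tested on simulated data of 11424 genes with 200 changed genes in each of 3 runs. It recovered 46.3%, 78.6% and 94.4% of 1.5-, 2- and 4-fold changes between sesamolin and lignan-free arrays, with 25 false calls among 473. A further 10 calls lay among the 60 genes of the lists that were also shifted in the simulation.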

Results

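Liver RNA was profiled on 20 Affymetrix arrays, 1 array per rat, in 4 diet groups of male Sprague-Dawley rats with 5 arrays each. The diets were lignan-free or held 0.2% of sesamin, episesamin or sesamolin and were fed for 15 d. Sesamin and episesamin are furofuran lignans of sesame and are epimers that differ in the configuration at the attachment of one of their methylenedioxyphenyl groups. Sesamolin carries an ether oxygen between one methylenedioxyphenyl group and the furofuran ring. Mean raw intensity per array ranged from 159 to 271, with group means of 247 ± 29.2 for lignan-free, 236 ± 27.6 for sesamin, 213 ± 36.1 for episesamin and 221 ± 45.3 for sesamolin (SD, n = 5). No lignan group differed from the lignan-free group in this brightness (exact permutation p = 0.54, 0.151 and 0.262, two-sided, n = 5 per group). The number of arrays limits the precision of every value. Log2 changes are given ± SE from a limma fit to all 20 arrays (n = 5 rats per diet), and levels are normalized intensities, mean ± SD of 5 rats.

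The first comparison asked which liver transcripts differed after feeding sesamin. Transcripts of fatty acid oxidation led the response. The acyl-CoA thioesterase Acot1 rose from 7.42 ± 3.39, which lies below the filter level of 17.8, to 1310 ± 923, a log2 change of 6.36 ± 0.36 (n = 5, adjusted p = 2.34e-09). A log2 value against a level below the filter depends on the offset (5.53 with an offset of 16 and 7.27 with none). Against the filter level the rise was at least 59-fold. Eci1, an enoyl-CoA isomerase of mitochondria, rose by 2.04 ± 0.12, or 4.13-fold (adjusted p = 2.34e-09). The thioesterases Acot2, Acot3 and Acot4 rose by 1.89 ± 0.13, 1.86 ± 0.23 and 1.79 ± 0.20. The carnitine acyltransferases Crot, of peroxisomes, and Crat rose by 1.81 ± 0.12 and 1.73 ± 0.19. Of 11576 genes tested, 46 were higher and 4 were lower with sesamin than without lignan, 22 of them by at least 2-fold.

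Each of 30 gene lists was compared with all other genes by camera. Of 21 measured genes of peroxisomal fatty acid oxidation, 6 rose and none fell (10 higher adjusted over the list alone). The mean was 0.55 (camera adjusted p = 2.38e-24; adjusted p = 2.37e-05 with an estimated correlation). They included Ech1, a dienoyl-CoA isomerase, at 1.69 ± 0.14 and Ehhadh, the peroxisomal bifunctional enzyme, at 1.61 ± 0.19. Of 25 genes of mitochondrial fatty acid oxidation, 11 rose and none fell (19 higher adjusted over the list alone). The mean was 0.58 (adjusted p = 1.79e-42 and, with an estimated correlation, 6.2e-05). Members included Decr1, a dienoyl-CoA reductase, at 0.93 ± 0.08. Fatty acid uptake, activation and acyl-CoA hydrolysis had 6 of 25 genes higher and none lower (10 and 3 adjusted over the list alone). Its mean, which Acot1 lifts with each lignan, was 0.55 (adjusted p = 8.51e-10 and, with an estimated correlation, 0.0114). Vnn1, a pantetheinase, was at 1.75 ± 0.19.

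Pex11a, which acts in peroxisome division, rose by 1.64 ± 0.23 and was the only member of 17 in the peroxisome biogenesis list to pass (2 adjusted over the list alone; list adjusted p = 0.0136, and adjusted p = 0.0527 with an estimated correlation). Acat1, the mitochondrial acetoacetyl-CoA thiolase, rose by 0.63 ± 0.10 and was the only member to pass of 8 in the ketone body synthesis list (list adjusted p = 0.00194; adjusted p = 0.0527 with an estimated correlation). Of 11 genes of microsomal omega-oxidation, 3 rose, including the fatty acid omega-hydroxylases Cyp4a1 at 1.45 ± 0.10 and Cyp4a3 at 0.84 ± 0.12 (list adjusted p = 0.0136; adjusted p = 0.101 with an estimated correlation). Aig1 rose by 1.98 ± 0.19, Colq, the collagen tail of acetylcholinesterase, by 1.90 ± 0.25, and Plin5, a lipid droplet coat protein, by 0.69 ± 0.12.

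The 4 lower genes were Pklr, the liver pyruvate kinase, at -0.64 ± 0.13 (adjusted p = 0.0371), Gpi, phosphoglucose isomerase, at -0.53 ± 0.11 (adjusted p = 0.0293), the secreted Wnt antagonist Frzb at -0.81 ± 0.17 (adjusted p = 0.0383) and Tsx at -2.11 ± 0.45 (adjusted p = 0.0457). Tsx lay outside the rule for named genes and was chosen after its value was seen. It lay below the filter level on 4 of 5 sesamin arrays, against which it was at least 4.61-fold lower, and with no offset it did not pass (adjusted p = 0.124). Fatty acid and triglyceride synthesis was lower as a list, with 26 of 28 members below 0 and a mean of -0.38, although only Pklr passed singly (2 lower adjusted over the list alone; list adjusted p = 7.17e-10; adjusted p = 0.108 with an estimated correlation). Glycolysis and gluconeogenesis had 2 of 23 genes lower, Pklr and Gpi (3 adjusted over the list alone; list adjusted p = 0.0459; adjusted p = 0.458 with an estimated correlation). Cholesterol synthesis and uptake had a mean of -0.16 with 0 of 21 genes past the threshold (list adjusted p = 0.0198; 0.621 with an estimated correlation).

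Markers of other liver cells were lower beside these groups, with 0 single genes past the threshold. Kupffer cell and macrophage markers had a mean of -0.22 (14 genes, adjusted p = 0.000369; adjusted p = 0.262 with an estimated correlation), endothelial markers -0.14 (14 genes, 0.0226; adjusted p = 0.258 with an estimated correlation) and stellate cell and fibroblast markers -0.13 (17 genes, 0.0374; adjusted p = 0.404 with an estimated correlation). Without normalization between arrays 18 genes were called, with only the groups compared in the fit 31, and without the 4 arrays numbered 1 in each group 30. The calls of Frzb, Gpi, Pklr, Decr1, Cyp4a3, Acat1 and Plin5 ended without normalization (adjusted p up to 0.982), and that of Acat1 under median scaling (0.159). Calls ended with only the groups compared for Pklr, Gpi, Tsx and Plin5 (up to 0.125), and without the 6 arrays of mean raw intensity below 200 for Frzb, Pklr, Gpi and Plin5 (up to 0.169). Without the arrays numbered 1 they ended for Frzb, Pklr, Tsx, Acat1 and Plin5 (up to 0.353), and with the mean of a gene's probe sets for Eci1, Frzb and Tsx (up to 0.553). Those of Frzb and Tsx ended with the brightness covariate (up to 0.0668), and those of Frzb, Pklr and Tsx with the actin covariate (up to 0.0703) and without the filter (up to 0.06). Leaving out 1 array ended the call of Frzb for any lignan-free or sesamin array or episesamin replicate 4 (adjusted p up to 0.144). That of Pklr ended for any lignan-free array, sesamin replicates 1, 3 and 4, episesamin 2, 4 and 5 and sesamolin 3, 4 and 5 (up to 0.137). That of Gpi ended for lignan-free 2, 3 and 4 and sesamin 3, 4 and 5 (up to 0.1). That of Tsx ended for 15 of the 20 arrays, all except lignan-free 5, sesamin 2, episesamin 2 and 3 and sesamolin 4 (up to 0.156). Single arrays lay far from the other 4 of their diet in Eci1 (lignan-free replicate 4), Tsx (sesamin 2) and Cyp4a3 (sesamin 4).

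The list call of peroxisome biogenesis ended without normalization and under median scaling (adjusted p up to 0.0903). That of omega-oxidation ended with only the groups compared, without the arrays numbered 1 and without lignan-free 1 (adjusted p up to 0.211). That of cholesterol synthesis and uptake ended under median scaling, with only the groups compared, by fry, without the arrays numbered 1 and without lignan-free 1, 2, 4 or 5 or sesamin 4 (adjusted p up to 0.476). That of glycolysis and gluconeogenesis ended without normalization, under median scaling, with only the groups compared, by fry, without the filter, with the actin covariate, without the arrays numbered 1 and without lignan-free 2, 3, 4 or 5, sesamin 1, 3 or 4, episesamin 2 or 4 or sesamolin 4 or 5 (adjusted p up to 0.269). That of Kupffer markers ended by fry (adjusted p = 0.141). That of stellate cell and fibroblast markers ended with only the groups compared, by fry, with array weights, with the actin covariate, without the 6 dim arrays and without lignan-free 3 or sesamin 1, 2 or 5 (adjusted p up to 0.621). That of endothelial markers ended by fry, with the mean of probe sets, without the 6 dim arrays and without lignan-free 3 or 4 or sesamin 5 (adjusted p up to 0.213).

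**Figure D1:**
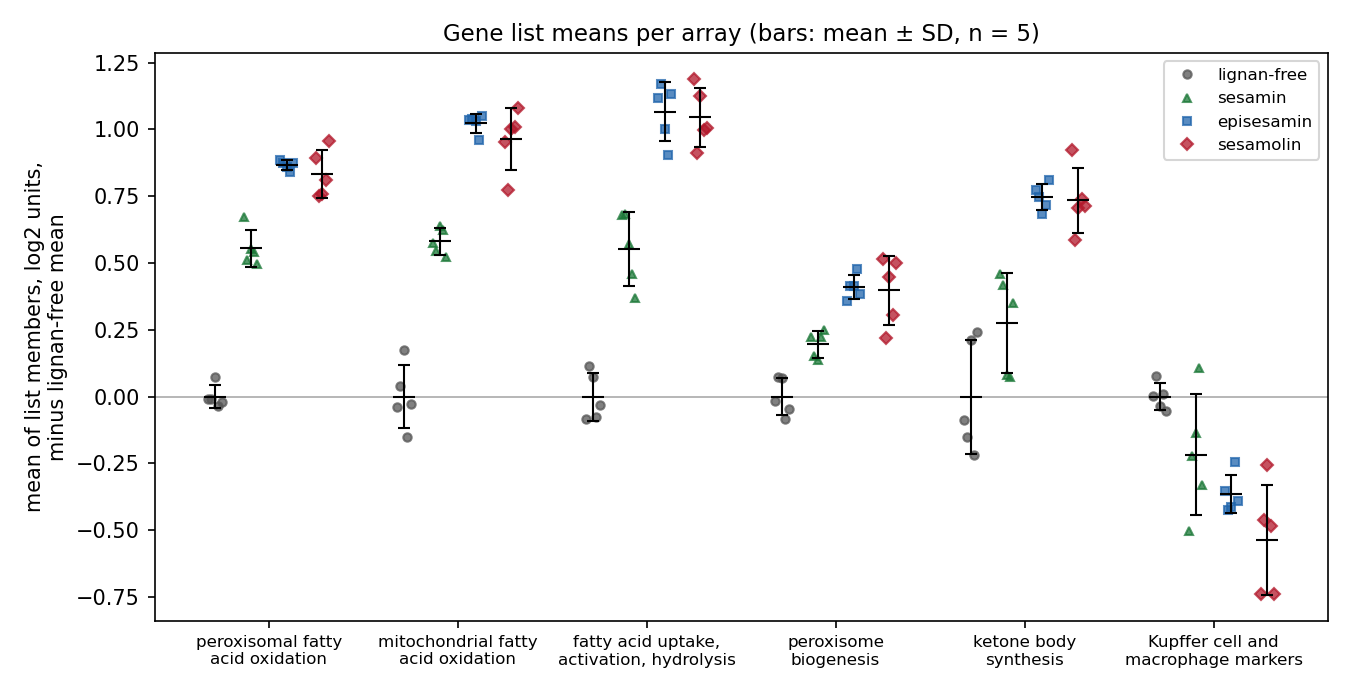
Mean of each list's genes per array, in log2 units relative to the lignan-free mean, for 5 fatty acid, peroxisome and ketone body lists and for Kupffer cell markers. Points are the 5 arrays of each diet and bars the mean ± SD. The mean for mitochondrial fatty acid oxidation was 0.58 with sesamin, 1.02 with episesamin and 0.96 with sesamolin.

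Episesamin, the epimer of sesamin, was compared with the lignan-free diet at the same dose and time. It raised many of the same kinds of transcripts by larger amounts. Acot1 reached 5883 ± 325, at least 329-fold higher since the lignan-free level lies below the filter. Its fitted log2 change of 8.83 ± 0.36 (n = 5, adjusted p = 1.02e-11) depends on the offset (7.99 with an offset of 16 and 9.75 with none). Crat rose by 3.49 ± 0.19 (11.2-fold), Ehhadh by 3.15 ± 0.19 (8.86-fold), Vnn1 by 3.05 ± 0.19 and Pex11a by 2.93 ± 0.23. Of 11576 genes tested, 337 were higher and 256 lower, 119 of them by at least 2-fold.

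Of the peroxisomal fatty acid oxidation genes, 12 of 21 rose and 1 fell, the same counts adjusted over the list alone. The mean was 0.87 (adjusted p = 9.35e-18 and, with an estimated correlation, 0.000104). Crot rose by 2.49 ± 0.12 and Ech1 by 2.46 ± 0.14. Mitochondrial fatty acid oxidation had 19 of 25 genes higher and none lower (21 higher adjusted over the list alone). The mean was 1.02 (adjusted p = 5.06e-39 and, with an estimated correlation, 0.000104). Eci1 rose by 2.77 ± 0.12, Acot2 by 2.77 ± 0.13 and Decr1 by 1.41 ± 0.08. Cpt1a, the liver carnitine palmitoyltransferase of the outer mitochondrial membrane, was at 0.37 ± 0.16 and did not pass (adjusted p = 0.211). Fatty acid uptake, activation and acyl-CoA hydrolysis had 11 of 25 genes higher and 2 lower (14 and 3 adjusted over the list alone). The mean was 1.07 (adjusted p = 4.38e-13 and, with an estimated correlation, 0.00167). Acot1 lifts this mean, and Acot3 rose by 3.41 ± 0.23. Peroxisome biogenesis had 5 of 17 genes higher and none lower (8 and 1 adjusted over the list alone; adjusted p = 3.31e-05; 0.00167 with an estimated correlation). Members included the import receptor Pex19 at 0.70 ± 0.11. Ketone body synthesis had 5 of 8 higher and none lower, the same counts adjusted over the list alone. The mean was 0.75 (adjusted p = 2.62e-07 and, with an estimated correlation, 0.00167). Members included Acat1 at 0.93 ± 0.10 and the monocarboxylate transporter Slc16a1 at 0.73 ± 0.13.

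Outside these lists, Hdc, the histidine decarboxylase that makes histamine, rose by 4.28 ± 0.66 (909 ± 640 against 25.4 ± 6.83), the kinase Nim1k by 3.83 ± 0.46, Aig1 by 3.57 ± 0.19, Colq by 3.54 ± 0.25 and Spmip11 by 3.0 ± 0.37 (at least 7.13-fold, from below the filter level on 3 of 5 lignan-free arrays). Chrna2, a nicotinic acetylcholine receptor subunit, rose by 3.36 ± 0.38, from 5.97 ± 6.83, below the filter level, to 110 ± 46.8, at least 5.79-fold. Among the omega-oxidation genes 4 of 11 rose and 1 fell (5 and 2 adjusted over the list alone), with Cyp4a1 at 1.94 ± 0.10 and Cyp4a3 at 1.0 ± 0.12. The list's mean was 0.24 and its median -0.05 (camera upward, adjusted p = 0.0334; adjusted p = 0.171 with an estimated correlation). Lipoproteins and lipid transport moved both ways, 4 higher and 4 lower of 25 (6 and 7 adjusted over the list alone), with a mean of 0.05, a median of -0.11 and no call (downward, adjusted p = 0.753). The lipid droplet proteins Cidea and Plin5 rose by 2.0 ± 0.19 and 1.59 ± 0.12. The apolipoproteins Apoa4 and Apoa2 were at -1.35 ± 0.19 and -0.66 ± 0.10.

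Targets of the drug-sensing receptors CAR and PXR had 5 of 22 genes higher and 1 lower (8 and 4 adjusted over the list alone). The mean was 0.26 (adjusted p = 0.00632; 0.161 with an estimated correlation). The retinaldehyde dehydrogenase Aldh1a1 rose by 2.51 ± 0.34, the carboxylesterase Ces2c by 1.53 ± 0.24 and Por, the electron donor of microsomal P450s, by 0.81 ± 0.16. Glutathione and Nrf2 targets had 3 of 33 genes higher and 1 lower (3 and 4 adjusted over the list alone) and no call (adjusted p = 0.895, mean -0.02, median 0.04), with the carbonyl reductase Cbr1 at 1.32 ± 0.17 and Mgst3 at 0.50 ± 0.09. Bile acid synthesis and transport had 3 of 22 genes higher and 2 lower (3 and 3 adjusted over the list alone) and no call (downward, adjusted p = 0.949, mean 0.10, median -0.07), with the uptake transporter Slco1a4 at 1.61 ± 0.24 and the sterol transporter Abcg5 at 1.70 ± 0.31 (at least 2.94-fold, from a level below the filter). UDP-glucuronosyltransferases and sulfotransferases had 1 of 18 genes higher and 2 lower (1 and 4 adjusted over the list alone) and no call (downward, adjusted p = 0.561, mean 0.03), with Papss2, a synthase of the sulfate donor, at -0.48 ± 0.10.

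In carbohydrate and lipid synthesis, Pklr was lower by a log2 change of -1.05 ± 0.13 (adjusted p = 5.8e-05), the glucose transporter Slc2a2 by -0.62 ± 0.09 and the acetyl-CoA synthetase Acss2 by -0.86 ± 0.19. Pdk4, a kinase that inactivates pyruvate dehydrogenase, was higher by 1.67 ± 0.29. Fatty acid and triglyceride synthesis had 1 of 28 genes higher and 4 lower (4 and 6 adjusted over the list alone; adjusted p = 0.0668) and glycolysis and gluconeogenesis 1 of 23 higher and 2 lower (1 and 4 adjusted over the list alone; adjusted p = 0.269), so neither list was called. Cholesterol synthesis and uptake had a mean of -0.34 with 1 of 21 genes lower (adjusted p = 0.000326; 0.361 with an estimated correlation). Amino acid breakdown and the urea cycle had 1 of 43 genes higher, Agxt at 0.52 ± 0.11, and 5 lower, among them the urea cycle enzyme Ass1 at -0.60 ± 0.12 (3 and 9 adjusted over the list alone; adjusted p = 0.00619; adjusted p = 0.234 with an estimated correlation). Oxidative phosphorylation had a mean of 0.08 with 1 of 32 genes higher (adjusted p = 0.00494; adjusted p = 0.171 with an estimated correlation), and endoplasmic reticulum stress and protein folding a mean of -0.13 with 2 of 23 lower (4 adjusted over the list alone; adjusted p = 0.006; adjusted p = 0.131 with an estimated correlation).

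Lower genes with episesamin included Myo7b, an unconventional myosin, at -2.11 ± 0.39, the ADP-ribosyltransferase Art4 at -1.61 ± 0.44, the tyrosine kinase Tnk2 at -1.48 ± 0.36, the mitochondrial carbonic anhydrase Car5a at -1.43 ± 0.22, the inositol phosphate synthase Isyna1 at -1.35 ± 0.21, the transcription factor Hes6 at -1.35 ± 0.29 and Ssbp4 at -1.29 ± 0.35. The episesamin levels of Art4, Tnk2 and Ssbp4 (16.3, 10.3 and 9.04) lie below the filter level, so these 3 log2 values depend on the offset. Against that level the genes were at least 2.35-, 1.79- and 1.51-fold lower, and with no offset Art4 and Ssbp4 did not pass (adjusted p = 0.0608 and 0.0709). Acute phase and inflammation had 2 of 29 genes lower (3 adjusted over the list alone). Members included the copper carrier Cp at -0.40 ± 0.08. The mean was -0.23 (adjusted p = 0.0195; 0.313 with an estimated correlation). Beside these groups, Kupffer cell and macrophage markers had 4 of 14 genes lower, the same adjusted over the list alone, including the complement gene C1qa at -0.60 ± 0.13, and a mean of -0.37 (adjusted p = 2.29e-05; adjusted p = 0.171 with an estimated correlation).

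Without normalization between arrays 262 genes were called, 73 higher and 189 lower, with a median change of all genes of -0.25. With only the groups compared in the fit 352 were called. Without the 6 arrays of mean raw intensity below 200 there were 272, and without the 4 arrays numbered 1 there were 342. Leaving out lignan-free replicate 4 or 5 or episesamin replicate 3 or 4 gave 376, 370, 380 and 388 calls. Without normalization the calls of Pex19, Acat1, Slc16a1, Por, Agxt, C1qa, Cp, Papss2 and Mgst3 ended (adjusted p up to 0.384), and under median scaling those of Pex19 and Agxt (up to 0.0666). Without the 6 dim arrays those of Art4, Tnk2, Ssbp4, Agxt, C1qa and Cp ended (up to 0.121), and without the arrays numbered 1 those of Art4, Tnk2, Hes6, Ssbp4, Por and Acss2 (up to 0.167). Calls also ended with the brightness covariate for Art4 and Tnk2 (up to 0.0835), with the actin covariate for Art4 (0.0725) and without the filter for Art4 and Ssbp4 (up to 0.054). They ended with only the groups compared for Acss2 (0.0707) and with the mean of probe sets for Papss2 (0.112). Single omissions ended the call of Art4 for any lignan-free array, sesamin replicate 4 and episesamin 1, 3 and 4 (adjusted p up to 0.107). That of Tnk2 ended for lignan-free 2 and 4 and episesamin 1, 3 and 4 (up to 0.0655). That of Ssbp4 ended for any lignan-free array and episesamin 1, 4 and 5 (up to 0.0941). Single arrays lay far from the other 4 of their diet in Eci1 (lignan-free replicate 4), Chrna2 and Pdk4 (lignan-free 5), Ces2c and Por (lignan-free 3) and Acat1 (episesamin 5).

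The list call of omega-oxidation ended with only the groups compared, with array weights, with the brightness covariate, without the arrays numbered 1 and without lignan-free 1 or episesamin 1 or 5 (adjusted p up to 0.141). That of cholesterol synthesis and uptake ended by fry (adjusted p = 0.0565). That of oxidative phosphorylation ended without normalization and under median scaling (adjusted p up to 0.505). That of acute phase and inflammation ended without normalization, under median scaling and without episesamin 1 (adjusted p up to 0.233).

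**Figure D2:**
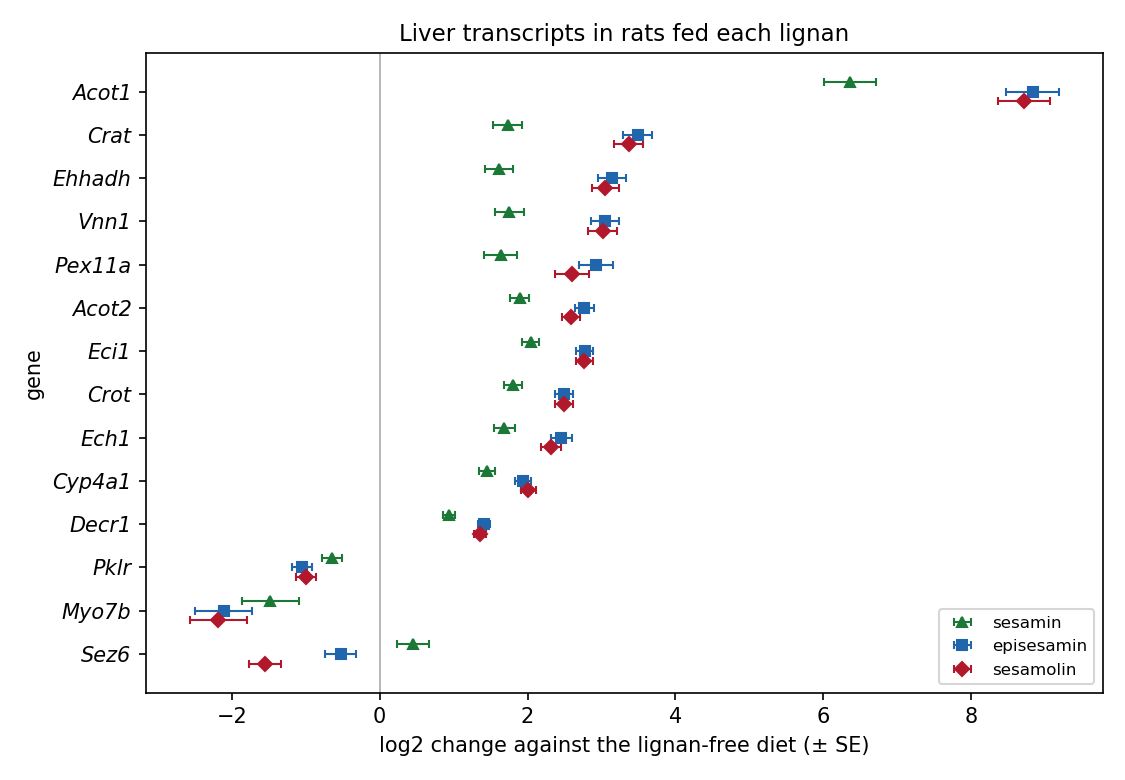
Log2 change against the lignan-free diet, ± SE, of 14 named genes with sesamin, episesamin and sesamolin (n = 5 rats per diet). Acot1, whose lignan-free level lies below the filter so that its value depends on the offset, changed by 6.36, 8.83 and 8.71 with the 3 lignans, and Pklr by -0.64, -1.05 and -1.0.

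Sesamolin was compared with the lignan-free diet in the same way. Acot1 reached 5472 ± 853, at least 303-fold higher since the lignan-free level lies below the filter. Its fitted log2 change of 8.71 ± 0.36 (n = 5, adjusted p = 1.06e-11) depends on the offset (7.87 with an offset of 16 and 9.64 with none). Crat rose by 3.37 ± 0.19 (10.3-fold), Ehhadh by 3.05 ± 0.19 (8.3-fold), Vnn1 by 3.02 ± 0.19, Eci1 by 2.77 ± 0.12 and Pex11a by 2.60 ± 0.23. Of 11576 genes tested, 380 were higher and 342 lower, 120 of them by at least 2-fold.

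Peroxisomal fatty acid oxidation had 13 of 21 genes higher and 1 lower (13 and 2 adjusted over the list alone). The mean was 0.83 (adjusted p = 4.08e-17 and, with an estimated correlation, 0.000203). Members included Crot at 2.50 ± 0.12 and Ech1 at 2.32 ± 0.14. Mitochondrial fatty acid oxidation had 18 of 25 higher and none lower (21 and 1 adjusted over the list alone). The mean was 0.96 (adjusted p = 7.48e-35 and, with an estimated correlation, 0.000203). Members included Acot2 at 2.59 ± 0.13 and Decr1 at 1.36 ± 0.08. Cpt1a was at 0.51 ± 0.16 and did not pass (adjusted p = 0.0733). Fatty acid uptake, activation and acyl-CoA hydrolysis had 12 of 25 higher and 2 lower (15 and 3 adjusted over the list alone). The mean was 1.05 (adjusted p = 1.02e-12 and, with an estimated correlation, 0.0024). Members included Acot3 at 3.20 ± 0.23. Peroxisome biogenesis had 5 of 17 higher and none lower (7 and 1 adjusted over the list alone; adjusted p = 3.05e-05; 0.0024 with an estimated correlation). Members included Pex19 at 0.74 ± 0.11. Ketone body synthesis had 5 of 8 higher and none lower (6 adjusted over the list alone; adjusted p = 1.13e-06; 0.00278 with an estimated correlation). Members included Acat1 at 0.85 ± 0.10. Omega-oxidation had 3 of 11 higher and 2 lower (4 and 2 adjusted over the list alone), with Cyp4a1 at 2.01 ± 0.10 and Cyp4a3 at 1.04 ± 0.12, a mean of 0.15, a median of -0.22 and no call (upward, adjusted p = 0.212).

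Hdc rose by 4.35 ± 0.66, Aig1 by 3.71 ± 0.19, Nim1k by 3.62 ± 0.46, Chrna2 by 3.60 ± 0.38 (at least 6.89-fold, from below the filter level), Colq by 3.38 ± 0.25 and Spmip11 by 3.07 ± 0.37 (at least 7.47-fold). The lipid droplet genes Cidea, Plin5 and Plin2 rose by 2.12 ± 0.19, 1.56 ± 0.12 and 0.65 ± 0.12, in a lipoprotein and lipid transport list with 4 of 25 genes higher and 3 lower (4 and 6 adjusted over the list alone) and no call (downward, adjusted p = 0.782, mean 0.06, median -0.09). CAR and PXR targets had 5 of 22 higher and none lower (10 and 1 adjusted over the list alone). Members included Aldh1a1 at 2.26 ± 0.34 and Ces2c at 1.35 ± 0.24. The mean was 0.27 (adjusted p = 0.00137; 0.0706 with an estimated correlation). Glutathione and Nrf2 targets had 4 of 33 higher and none lower (4 and 1 adjusted over the list alone; not called, adjusted p = 0.262). Members included Cbr1 at 1.10 ± 0.17 and Mgst3 at 0.43 ± 0.09.

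Pklr was lower by a log2 change of -1.0 ± 0.13, Slc2a2 by -0.76 ± 0.09 and the glucose-phosphate transporter Slc37a4 by -0.71 ± 0.12, and Pdk4 was higher by 1.57 ± 0.29, in a glycolysis and gluconeogenesis list with 1 of 23 higher and 3 lower (1 and 4 adjusted over the list alone; not called, adjusted p = 0.103). The triglyceride-forming acyltransferases moved apart, Dgat2 at -0.71 ± 0.11 and Dgat1 at 0.44 ± 0.10, and the transcription factor Mlxipl was at -0.55 ± 0.12. Fatty acid and triglyceride synthesis had 3 of 28 higher and 4 lower (4 and 7 adjusted over the list alone) and was not called (adjusted p = 0.163). Bile acid synthesis and transport had 2 of 22 higher, including Slco1a4 at 1.55 ± 0.24, and 2 lower, including the hydroxysteroid dehydrogenase Akr1c14 at -0.51 ± 0.09 (4 and 3 adjusted over the list alone; not called, downward with a positive mean of 0.05, adjusted p = 0.512). UDP-glucuronosyltransferases and sulfotransferases had 1 of 18 higher and 2 lower (4 and 3 adjusted over the list alone; not called, upward with a negative mean of -0.09, adjusted p = 0.901). Members included Papss2 at -0.62 ± 0.10. Cholesterol synthesis and uptake had a mean of -0.23 with 0 of 21 genes past the threshold (adjusted p = 0.0199; 0.557 with an estimated correlation).

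Amino acid breakdown and the urea cycle had 2 of 43 genes higher, including Agxt at 0.54 ± 0.11, and 5 lower, including Ass1 at -0.52 ± 0.12 (2 and 7 adjusted over the list alone; adjusted p = 0.00325; adjusted p = 0.176 with an estimated correlation). Oxidative phosphorylation had a mean of 0.08 with 0 of 32 genes past the threshold (adjusted p = 0.00696; 0.176 with an estimated correlation). Endoplasmic reticulum stress and protein folding had 3 of 23 genes lower, the same adjusted over the list alone, including the chaperone Hsp90b1 at -0.46 ± 0.09 (adjusted p = 0.00454; adjusted p = 0.0866 with an estimated correlation). Acute phase and inflammation had 1 of 29 higher and 4 lower (1 and 5 adjusted over the list alone; not called, adjusted p = 0.0574). Members included Cp at -0.36 ± 0.08. Sex-dependent and growth hormone-dependent genes had 1 of 28 lower, the growth factor carrier Igfbp3 at -0.63 ± 0.14 (2 higher and 2 lower adjusted over the list alone; not called, upward with a negative mean of -0.03, adjusted p = 0.669).

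Lower genes with sesamolin included Myo7b at -2.18 ± 0.39, Art4 at -1.81 ± 0.44, the pseudogene Syncrip-ps2 at -1.59 ± 0.30, Slfn4 at -1.57 ± 0.27, Sez6 at -1.55 ± 0.21, the aminopeptidase Xpnpep2 at -1.34 ± 0.18, Polg2, the accessory subunit of the mitochondrial DNA polymerase, at -1.28 ± 0.26, and the aldo-keto reductase Akr1c15 at -1.19 ± 0.27. The sesamolin levels of Art4, Syncrip-ps2 and Slfn4 (12.6, 11.1 and 16.1) lie below the filter level, against which they were at least 2.61-, 2.17- and 2.6-fold lower. Beside these groups, Kupffer cell and macrophage markers had 8 of 14 genes lower (11 adjusted over the list alone). The mean was -0.54 (adjusted p = 1.16e-08; 0.0706 with an estimated correlation). C1qa was at -0.87 ± 0.13, C1qc at -0.80 ± 0.14, Aif1 at -0.99 ± 0.18 and the protease Ctss at -0.60 ± 0.13. Lymphocyte and neutrophil markers had a mean of -0.36 with 0 of 14 genes past the threshold (adjusted p = 0.0177; adjusted p = 0.157 with an estimated correlation), stellate cell and fibroblast markers -0.20 with 1 of 17 lower, Colec11 at -0.36 ± 0.07 (0.00696; adjusted p = 0.187 with an estimated correlation), and endothelial markers -0.18 with 2 of 14 lower (0.0372; adjusted p = 0.237 with an estimated correlation).

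Without normalization between arrays 264 genes were called, 68 higher and 196 lower, with a median change of all genes of -0.22. With only the groups compared in the fit 372 were called. Without the 6 arrays of mean raw intensity below 200 there were 371, and without the 4 arrays numbered 1 there were 366. Without normalization the calls of Pex19, Acat1, Plin2, Cbr1, Mgst3, Dgat1, Agxt, Ctss, Colec11, Cp, Hsp90b1 and Igfbp3 ended (adjusted p up to 0.541), and under median scaling those of Mgst3, Dgat1 and Cp (up to 0.0832). Without the 6 dim arrays those of Polg2, Akr1c15, Plin2, Agxt, Colec11, Cp and Igfbp3 ended (up to 0.105), and without the arrays numbered 1 those of Art4, Mlxipl and Ctss (up to 0.0878). Calls also ended with only the groups compared for Akr1c15, Dgat1 and Ass1 (up to 0.0671) and with the mean of probe sets for Plin2 and Cp (up to 0.729). Cpt1a passed with trended and robust eBayes (adjusted p = 0.0451) and with the filter at the 60th percentile (0.0496), and also without sesamin replicate 1 or 4. Leaving out lignan-free replicate 5 or sesamolin replicate 5 gave 460 and 472 calls, and leaving out sesamolin replicate 3 or 5 ended the call of Art4 (adjusted p up to 0.0538). Single arrays lay far from the other 4 of their diet in Crat, Art4 and Hes6 (sesamolin replicate 2), Aif1 (sesamolin 5), Slfn4 and Ces2c (lignan-free 3), Xpnpep2 and Eci1 (lignan-free 4) and Chrna2 and Pdk4 (lignan-free 5).

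The list call of cholesterol synthesis and uptake ended without normalization, under median scaling, by fry, with the brightness covariate, without the arrays numbered 1 and without lignan-free 1, 4 or 5 or sesamolin 5 (adjusted p up to 0.199). That of oxidative phosphorylation ended without normalization (adjusted p = 0.284). That of endoplasmic reticulum stress and protein folding ended without normalization (adjusted p = 0.0619). That of lymphocyte and neutrophil markers ended without normalization, under median scaling, with the stricter filter, without the 6 dim arrays and without sesamolin 5 (adjusted p up to 0.333). That of stellate cell and fibroblast markers ended without lignan-free 3 (adjusted p = 0.0835). That of endothelial markers ended with only the groups compared, with the mean of probe sets, with the actin covariate and without lignan-free 3 or 4 or sesamolin 1 or 2 (adjusted p up to 0.12).

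The genes called with the 3 lignans overlapped. Of the 50 genes called with sesamin, 48 were also called in the same direction with episesamin and 47 with sesamolin. In all, 46 higher and 2 lower genes were shared with episesamin where independent calls would give 1.34 and 0.0885. Episesamin and sesamolin shared 236 higher and 139 lower genes, against 11.1 and 7.56, and 0 genes were called in opposite directions in any pair. The comparisons share the lignan-free arrays. In 50 simulations with no effect the overlap was 0, but with no effect almost no gene is called, so this value does not show what the shared arrays add. The covariance of the log2 changes over all genes was 0.061 (sesamin and episesamin), 0.0576 (sesamin and sesamolin) and 0.108 (episesamin and sesamolin), where the simulations gave 0.0269, 0.0267 and 0.0268. The same sign was seen in 68.7%, 68.2% and 78.2% of genes, against 66.6%, 66.5% and 66.8% simulated. When those arrays were split into parts of 2 and 3, with each lignan compared with its own part, the overlaps over 20 splits were 20 to 38, 20 to 37 and 114 to 132 genes. With these fewer control arrays the calls also fell, to a median of 34, 246 and 277 for sesamin, episesamin and sesamolin, beside median overlaps of 32, 31.5 and 123.

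At the same dose and time, the epimers were compared directly. Episesamin gave higher levels than sesamin for the leading fatty acid genes: Acot1 by a log2 difference of 2.47 ± 0.36 (95% interval 1.72 to 3.22, n = 5 per diet, adjusted p = 0.00106), Crat by 1.76 ± 0.19 (1.35 to 2.16) and Ehhadh by 1.53 ± 0.19 (1.14 to 1.93). Pex11a was higher by 1.29 ± 0.23, the peroxisomal thioesterase Acot8 by 1.16 ± 0.11, Acot7 by 1.27 ± 0.17 and Acad11, an acyl-CoA dehydrogenase, by 0.73 ± 0.10. Chrna2 (at least 4.93-fold, from a sesamin level below the filter), Spmip11 and Ugt2b1 were higher by 2.49 ± 0.38, 2.25 ± 0.37 and 2.07 ± 0.39, Dact2 by 1.65 ± 0.34, Pdk4 by 1.52 ± 0.29, Cidea by 1.43 ± 0.19, Cbr1 by 0.94 ± 0.17 and Plin5 by 0.90 ± 0.12. Of 11576 genes tested, 95 were higher and 47 lower with episesamin.

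The same 5 lists kept a call with an estimated correlation. Peroxisomal fatty acid oxidation had 8 of 21 genes higher and 1 lower (11 and 2 adjusted over the list alone), mean 0.31 (adjusted p = 0.00901 with an estimated correlation). Mitochondrial fatty acid oxidation had 13 of 25 higher and none lower (15 adjusted over the list alone), mean 0.44 (0.00901), and fatty acid uptake, activation and acyl-CoA hydrolysis 7 of 25 higher and none lower (11 adjusted over the list alone), mean 0.51 (0.00901). Peroxisome biogenesis had 3 of 17 higher (4 higher and 1 lower adjusted over the list alone; 0.0123). Ketone body synthesis had 2 of 8 higher, including Pdk4 (4 adjusted over the list alone; 0.0123). Amino acid breakdown and the urea cycle had 2 of 43 genes lower (4 adjusted over the list alone), including the lysine-degrading enzyme Aass at -0.59 ± 0.12. The mean was -0.21 (adjusted p = 1.62e-05; 0.0618 with an estimated correlation). Fatty acid and triglyceride synthesis was higher with episesamin by a mean of 0.17 (adjusted p = 0.0191; adjusted p = 0.577 with an estimated correlation), CAR and PXR targets by 0.15 (0.0291; adjusted p = 0.262 with an estimated correlation) and oxidative phosphorylation by 0.07 (0.00139; adjusted p = 0.127 with an estimated correlation). Cholesterol synthesis and uptake was lower by a mean of -0.17 (0.0291; adjusted p = 0.58 with an estimated correlation), endoplasmic reticulum stress and protein folding by -0.10 (0.00521; adjusted p = 0.0999 with an estimated correlation) and acute phase and inflammation by -0.20 (0.0116; adjusted p = 0.262 with an estimated correlation). Kupffer cell and macrophage markers differed by a mean of -0.15 with 0 of 14 genes past the threshold (adjusted p = 0.0274; 0.506 with an estimated correlation).

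Lower with episesamin than with sesamin were Stac3 at -2.20 ± 0.41, A2ml1 at -1.63 ± 0.39, Car5a at -1.43 ± 0.22, Doc2b at -1.22 ± 0.29, the asparaginase Asrgl1 at -1.10 ± 0.25 and Apoa4 at -1.04 ± 0.19. The episesamin levels of A2ml1 and Doc2b (7.2 and 6.56) lie below the filter level, so both log2 values depend on the offset. Against that level they were at least 1.8- and 1.29-fold lower, and with no offset neither passed (adjusted p = 0.109 and 0.0569). The count of 142 was 12 without normalization between arrays, 65 under median scaling, 82 with only the groups compared in the fit, 78 with the actin 3' to 5' ratio as a covariate, 84 without the 6 arrays of mean raw intensity below 200, 76 without the 4 arrays numbered 1, and 92, 84, 94 and 86 without sesamin replicate 4, sesamin 5, episesamin 2 and episesamin 5. Without normalization the calls of Acot8, Acad11, Pex11a, Acot7, Dact2, Pdk4, Cidea, Plin5, Cbr1, A2ml1, Doc2b, Asrgl1 and Aass ended (adjusted p up to 0.391), and under median scaling those of A2ml1, Doc2b, Asrgl1 and Aass (up to 0.119). Without the 6 dim arrays those of Ugt2b1, Dact2, A2ml1, Doc2b, Asrgl1 and Aass ended (up to 0.234), and without the arrays numbered 1 those of Stac3, A2ml1, Doc2b, Asrgl1, Pdk4 and Cbr1 (up to 0.19). Calls ended with only the groups compared for Asrgl1, Pdk4 and Aass (up to 0.124), with the brightness covariate for Doc2b and Asrgl1 (up to 0.0737) and with the actin covariate for Dact2 and Asrgl1 (up to 0.109). They also ended without the filter (up to 0.0637) and with array weights (up to 0.0594) for A2ml1 and Doc2b, with the mean of probe sets for A2ml1 and Asrgl1 (up to 0.0938) and with trended and robust eBayes for Doc2b (0.0538). Single omissions ended the call of Dact2 for sesamin 4 (adjusted p = 0.0526). That of A2ml1 ended for 17 of the 20 arrays, all except lignan-free 3 and 4 and episesamin 3 (up to 0.146). That of Doc2b ended for any sesamin or episesamin array and sesamolin 1 and 3 (up to 0.107). That of Asrgl1 ended for sesamin 1, 2, 4 and 5 and episesamin 2, 3 and 5 (up to 0.0992). Single arrays lay far from the other 4 of their diet in Ugt2b1 (episesamin replicate 5).

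The list call of fatty acid and triglyceride synthesis ended by fry, without the arrays numbered 1 and without sesamin 1 or 4 or episesamin 2 or 5 (adjusted p up to 0.291). That of cholesterol synthesis and uptake ended without normalization, by fry, with array weights, with the brightness covariate, with the actin covariate, without the 6 dim arrays, without the arrays numbered 1 and without sesamin 2 or 5 or episesamin 1, 3 or 4 (adjusted p up to 0.438). That of CAR and PXR targets ended with only the groups compared, with array weights, without the filter, without the 6 dim arrays, without the arrays numbered 1 and without sesamin 2 or 5 or episesamin 1 or 5 (adjusted p up to 0.117). That of oxidative phosphorylation ended without normalization (adjusted p = 0.271). That of acute phase and inflammation ended without normalization, under median scaling and without sesamin 4 (adjusted p up to 0.226). That of Kupffer markers ended by fry and without sesamin 2, 3 or 4 or episesamin 1, 2 or 3 (adjusted p up to 0.304).

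Sesamolin, which differs from both by the ether oxygen, also exceeded sesamin at the same dose and time. Acot1 was higher by a log2 difference of 2.35 ± 0.36 (95% interval 1.61 to 3.10, n = 5 per diet, adjusted p = 0.00141), Crat by 1.63 ± 0.19 (1.23 to 2.04), Ehhadh by 1.44 ± 0.19 (1.05 to 1.83), Acot8 by 1.27 ± 0.11 and Acot7 by 1.22 ± 0.17. Cpt1b, the muscle-type carnitine palmitoyltransferase, was higher by 1.83 ± 0.25 (130 ± 37.1 against 31.8 ± 7.74). Chrna2 (at least 5.86-fold, from a sesamin level below the filter), Spmip11, Aig1 and Ugt2b1 were higher by 2.73 ± 0.38, 2.32 ± 0.37, 1.73 ± 0.19 and 1.64 ± 0.39, and Cidea, Pdk4, Plin5 and the aldehyde reductase Akr7a3 by 1.56 ± 0.19, 1.42 ± 0.29, 0.88 ± 0.12 and 0.70 ± 0.14. Of 11576 genes tested, 116 were higher and 94 lower with sesamolin.

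Peroxisomal fatty acid oxidation had 9 of 21 genes higher and 1 lower (11 and 2 adjusted over the list alone), mean 0.28 (adjusted p = 0.0179 with an estimated correlation), mitochondrial fatty acid oxidation 12 of 25 higher and none lower (14 and 2 adjusted over the list alone), mean 0.38 (0.0179), and fatty acid uptake, activation and acyl-CoA hydrolysis 7 of 25 higher and none lower (12 adjusted over the list alone), mean 0.49 (0.0179). Peroxisome biogenesis had 3 of 17 higher (5 higher and 1 lower adjusted over the list alone; 0.0188). Ketone body synthesis had 1 of 8 higher, Pdk4 (3 adjusted over the list alone; 0.0329). Glutathione and Nrf2 targets had 4 of 33 higher, the same adjusted over the list alone (adjusted p = 0.00828; adjusted p = 0.109 with an estimated correlation). Fatty acid and triglyceride synthesis was higher with sesamolin by a mean of 0.21 (adjusted p = 0.00632; adjusted p = 0.468 with an estimated correlation), CAR and PXR targets by 0.17 (0.00828; adjusted p = 0.127 with an estimated correlation) and oxidative phosphorylation by 0.07 (0.0027; adjusted p = 0.127 with an estimated correlation). Amino acid breakdown and the urea cycle was lower by a mean of -0.20 with 1 of 43 genes lower (8 adjusted over the list alone; 8.7e-06; adjusted p = 0.0531 with an estimated correlation), bile acid synthesis and transport by -0.08 (0.0209; adjusted p = 0.0707 with an estimated correlation) and endoplasmic reticulum stress and protein folding by -0.12 (0.0027; adjusted p = 0.0707 with an estimated correlation). Kupffer cell and macrophage markers had 2 of 14 lower (6 adjusted over the list alone), including C1qa at -0.63 ± 0.13. The mean was -0.32 (adjusted p = 2.2e-05; 0.127 with an estimated correlation).

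Lower with sesamolin than with sesamin were Stac3 at -2.73 ± 0.41, Sez6 at -2.0 ± 0.21, Asrgl1 at -1.80 ± 0.25, Mtfr2 at -1.49 ± 0.34 (2.89 ± 1.60, below the filter level, against 18.9 ± 5.96), Slfn4 at -1.46 ± 0.27, Syncrip-ps2 at -1.42 ± 0.30, Papss2 at -0.63 ± 0.10 and Slc2a2 at -0.45 ± 0.09. Against the filter level Mtfr2, Slfn4 and Syncrip-ps2, all below it with sesamolin, were at least 1.02-, 2.4- and 1.9-fold lower, and with no offset Mtfr2 did not pass (adjusted p = 0.598). The count of 210 was 23 without normalization between arrays, 81 under median scaling, 52 with only the groups compared in the fit, 99 without the 6 arrays of mean raw intensity below 200, 106 without the 4 arrays numbered 1, and 134, 135, 118 and 114 without sesamin replicate 3, sesamin 4, sesamin 5 and sesamolin 3. Without normalization the calls of Ugt2b1, Plin5, Acot7, Pdk4, Akr7a3, C1qa, Slc2a2 and Papss2 ended (adjusted p up to 0.427), and under median scaling those of Akr7a3, C1qa and Slc2a2 (up to 0.107). With only the groups compared those of Acot1, Ugt2b1, Slfn4, Syncrip-ps2, Pdk4, C1qa and Slc2a2 ended (up to 0.124), and without the 6 dim arrays those of Ugt2b1, Mtfr2, Akr7a3, C1qa and Slc2a2 (up to 0.22). Calls also ended without the arrays numbered 1 for Ugt2b1, Mtfr2, Slfn4 and Pdk4 (up to 0.119) and with the mean of probe sets for Mtfr2 and Papss2 (up to 0.0781). Single omissions ended the call of Ugt2b1 for sesamin 2, 3, 4 and 5 and sesamolin 2, 3 and 5 (adjusted p up to 0.0991). That of Mtfr2 ended for sesamin 1, 3 and 5 and sesamolin 1, 3, 4 and 5 (up to 0.0703). That of Syncrip-ps2 ended for sesamin 5 and sesamolin 5 (up to 0.0557). Single arrays lay far from the other 4 of their diet in Crat (sesamolin replicate 2) and Syncrip-ps2 (sesamin 2).

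The list call of fatty acid and triglyceride synthesis ended by fry and without sesamin 4 (adjusted p up to 0.201). That of bile acid synthesis and transport ended without normalization, under median scaling and without sesamin 3 (adjusted p up to 0.231). That of CAR and PXR targets ended without the 6 dim arrays (adjusted p = 0.0921). That of oxidative phosphorylation ended without normalization (adjusted p = 0.133). That of endoplasmic reticulum stress and protein folding ended without normalization (adjusted p = 0.0638).

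Between sesamolin and episesamin 0 of 11576 genes passed the threshold in the limma fit. In the same fit 662 genes had an unadjusted p under 0.05, where 579 would be expected by chance. The differences in the leading genes were small beside their changes: Acot1 -0.12 (95% interval -0.87 to 0.63), Ehhadh -0.09 (-0.49 to 0.30), Acot2 -0.18 (-0.44 to 0.08), Pex11a -0.33 (-0.81 to 0.15) and Cyp4a1 0.07 (-0.14 to 0.29). Of the 940 genes called against the lignan-free diet with either lignan, 865 had a 95% interval of the difference within a log2 value of 1 on either side of 0, and the median half-width of these 940 intervals was 0.27. Within a log2 value of 0.58 there were 673. Of all 11576 genes 10241 also lay within 1, so that margin says little about the called genes. The smallest adjusted p was that of Akr7a3, higher with sesamolin by 0.77 ± 0.14 (0.48 to 1.07, adjusted p = 0.368), and Apoa2 was at 0.46 ± 0.10 (adjusted p = 0.513). With 200 changed genes per simulated run, 77.1% of 2-fold and 42.8% of 1.5-fold differences were recovered, which may exceed the power here.

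The 5 fatty acid, peroxisome and ketone body lists differed between sesamolin and episesamin by means of -0.06 to -0.01 and none was called, with mitochondrial fatty acid oxidation at -0.06 (adjusted p = 0.163). Kupffer cell and macrophage markers were the only list called, with a mean of -0.17 and 0 of 14 genes past the threshold (adjusted p = 0.0188; adjusted p = 0.69 with an estimated correlation). Akr7a3 passed without lignan-free replicate 2 or 3 (adjusted p = 0.026 and 0.0325), Ifit1 without episesamin replicate 4 (1.66 ± 0.20, adjusted p = 0.00159) or without the 6 arrays of mean raw intensity below 200, and Ccna1 without the filter on dim probe sets (-1.39 ± 0.20, adjusted p = 0.0256). Ccna1 is not among the 11576 genes, lies outside the rule for named genes and was chosen after its value was seen. The Kupffer list was not called without episesamin replicate 1 or 4 (adjusted p = 0.0629 and 0.101) or sesamolin replicate 1 or 5 (0.273 and 0.14), nor without normalization between arrays (0.0536), with the actin covariate (0.248), without the 6 arrays of mean raw intensity below 200 (0.357), without the 4 arrays numbered 1 (0.306) or by fry (0.693).

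**Figure D3:**
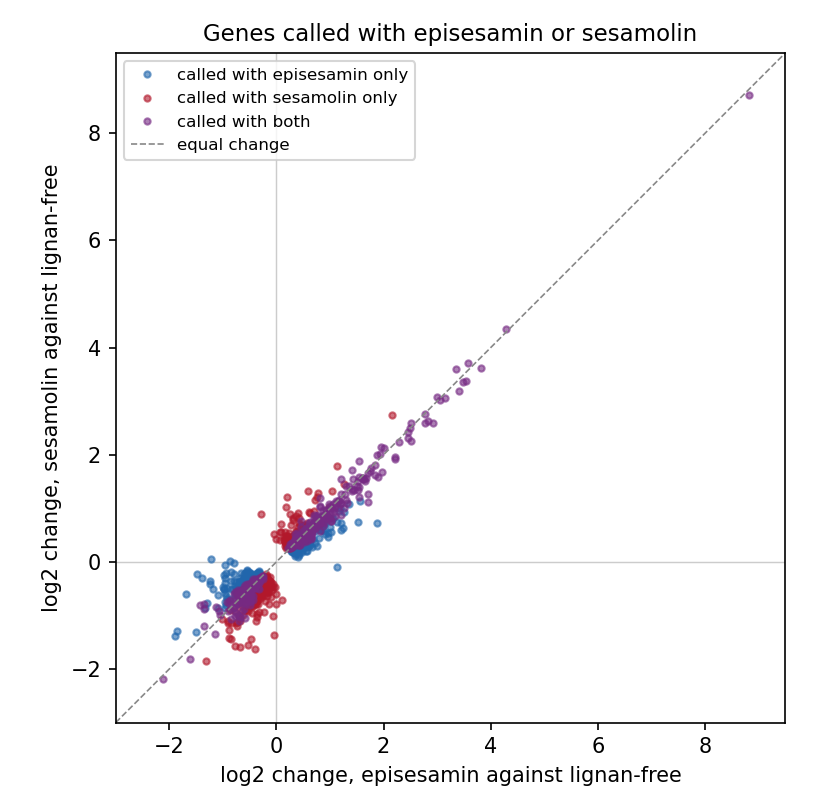
Log2 change with episesamin (x axis) and with sesamolin (y axis) against the lignan-free diet for the 940 genes called with either lignan, coloured by the diet or diets in which they were called. The dashed line marks equal change. The 375 genes called with both lie near that line, and 0 genes were called in opposite directions.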

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

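The tests in this part were set before the values were seen, except that of Tsx, a gene chosen after its value was seen. Each named gene, list score and array measure was examined within each diet for 1 array lying apart from the other 4, by the gap to its nearest neighbour over the whole range with a limit of 0.71. Of 484 groups, 30 held such an array: 21 of 340 for genes, 9 of 120 for list scores and 0 of 24 for array measures. Chance alone gives about 1 in 20, which is close to these shares. No biological explanation was tested for any single array.

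In normalized intensity, with the range of the other 4 arrays in brackets, the lignan-free arrays apart were replicate 4 for Eci1 at 1203 (1624 to 1749) and Xpnpep2 at 357.5 (231.7 to 267.9), replicate 5 for Chrna2 at 18.09 (1.608 to 4.125) and Pdk4 at 1350 (576.4 to 678.1), replicate 3 for Slfn4 at 84.54 (42.73 to 51.48), Ces2c at 197.5 (93.17 to 120.5) and Por at 823.2 (422.5 to 504.9), and replicate 2 for Acot8 at 262.2 (226.1 to 233.4). The sesamin arrays apart were replicate 5 for Isyna1 at 182 (86.14 to 111.4) and Aldh1a1 at 447.1 (1497 to 1726), replicate 2 for Syncrip-ps2 at 21.96 (38.37 to 42.53) and Tsx at 50.19 (12.9 to 16.21), and replicate 4 for Cyp4a3 at 9484 (5992 to 6907). The episesamin arrays apart were replicate 5 for Ugt2b1 at 3332 (1336 to 1770) and Acat1 at 3865 (5152 to 5290) and replicate 3 for Colec11 at 1044 (1008 to 1017). The sesamolin arrays apart were replicate 2 for Crat at 643 (1384 to 1621), Art4 at 31.13 (6.002 to 12.58) and Hes6 at 1284 (519.7 to 709.2), replicate 4 for A2ml1 at 28.36 (12.54 to 15.92) and replicate 5 for Aif1 at 50.07 (101.4 to 106.7).

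Among list scores, in log2 units relative to the lignan-free mean, lignan-free replicate 3 lay apart for peroxisomal fatty acid oxidation at 0.0745 (-0.0357 to -0.0081), cholesterol synthesis and uptake at -0.66 (0.0803 to 0.2102) and stellate cell and fibroblast markers at 0.4197 (-0.1758 to -0.0076). Lignan-free replicate 1 lay apart for lipoproteins and lipid transport at -0.1152 (0.0109 to 0.0601) and for glycolysis and gluconeogenesis at -0.1499 (0.0113 to 0.0631). Episesamin replicate 1 lay apart for glycolysis and gluconeogenesis at -0.2029 (-0.0294 to 0.0069) and for adipocyte and exocrine pancreas markers at 0.4514 (0.0504 to 0.0684), replicate 2 for omega-oxidation at 0.0344 (0.2832 to 0.3049) and replicate 4 for mitochondrial fatty acid oxidation at 0.9619 (1.032 to 1.051).

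Probe sets without a single gene symbol, which the comparisons above leave out, also held signal. Of 5173 tested, 8 were called with sesamin, 127 with episesamin and 149 with sesamolin against the lignan-free diet, all 8 of the first higher. Episesamin and sesamolin against sesamin gave 27 and 36, and sesamolin against episesamin 1. The largest increases against lignan-free were 3.36, 5.94 and 5.64 with sesamin, episesamin and sesamolin, in the same probe set. The largest decreases were -2.09 with episesamin and -1.75 with sesamolin, again in 1 probe set.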

How the results depend on the processing

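The tests without normalization between arrays, with the brightness and actin covariates, without the 6 dim arrays and without the 4 arrays numbered 1, and the parting of simulated genes by level, were chosen after the data were seen. Counts are in the order sesamin, episesamin and sesamolin against lignan-free (50, 593 and 722), then episesamin and sesamolin against sesamin (142 and 210) and sesamolin against episesamin (0). Without normalization they were 18, 262, 264, 12 and 23 for the first 5, while the median of all genes shifted by -0.0763, -0.2522 and -0.2165 against lignan-free. With only the groups compared in the fit they were 31, 352, 372, 82 and 52, and without the 4 arrays numbered 1 they were 30, 342, 366, 76 and 106, both with fewer arrays in the fit. Without the 6 dim arrays, episesamin and sesamolin against lignan-free gave 272 and 371, the pairs with sesamin 84 and 99, and sesamolin against episesamin 1. Median scaling gave 180 higher and 496 lower genes with episesamin and 178 and 457 with sesamolin, and 65 and 81 for the pairs with sesamin, and the actin covariate 78 for episesamin against sesamin. For sesamolin against episesamin, no filter and every probe set on its own gave 1 each. Of these moves, only the excess of lower genes under median scaling was tested for causes, as described below. The gene counts under the other settings lay within 1.5 times of those reported.

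With the replicate block the counts were 51, 697, 858, 155, 262 and 0, of which 43, 550, 678, 119 and 190 were shared with the calls reported. The block ended the calls of Frzb and Tsx with sesamin (adjusted p = 0.059 and 0.0543), Art4 with episesamin (0.0656), A2ml1 and Doc2b between episesamin and sesamin (0.0861 and 0.0584) and Ugt2b1 between sesamolin and sesamin (0.0549), and the list call of omega-oxidation with episesamin (0.0649). Residuals of same-number arrays correlated above 0.1 in 6 of 6 pairs for number 1 (0.127 to 0.246), in 1, 2, 0 and 1 of 6 for numbers 2 to 5 and in 2 of 120 other pairs. Not every pair exceeded 0.1, so the main fit did not pair arrays by number. Yet 11 of 20 arrays correlated best with their own number (4 expected). Number 1 arrays shared structure, with second component scores of 10.32 to 24 (others up to 7.94).

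Of 71 list calls, 23 were kept with an estimated correlation, 54 with fry, 61 under median scaling and 55 without normalization, and 0 changed direction in any of 37 settings. The lists called were 3 for sesamin, 5 for each of episesamin and sesamolin against lignan-free and each pair with sesamin, and 0 for sesamolin against episesamin with an estimated correlation. Fry called 7 for sesamin and 0 for sesamolin against episesamin, and the latter had 0 without the arrays numbered 1. The calls lost most often were cell cycle with sesamolin, in 22 of 37 settings, and glycolysis with sesamin, in 19. The 5 fatty acid, peroxisome and ketone body lists were lost in 0 settings for episesamin and sesamolin against lignan-free or sesamin.

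Leaving out 1 array at a time gave 35 to 52, 370 to 632, 460 to 720, 84 to 153, 114 to 223 and 0 to 1 genes, and 0 to 3 lists for sesamolin against episesamin. That list count was 0 without episesamin 1 or sesamolin 1, 2 without sesamolin 4 and 3 without episesamin 5 or sesamolin 5, and the gene count was 1 without lignan-free 2, lignan-free 3 or episesamin 4. The arrays behind the other moves are named with the results. Of the named-gene values under the alternatives, 6022 kept direction and side of the threshold, 299 fell short of it, 6 newly passed and 1 changed sign: Ehhadh between sesamolin and episesamin, not called, was 0.0553 without sesamolin replicate 2 and -0.16 without episesamin replicate 4, its lowest. Signal limits the dim genes: simulated 1.5-fold changes between sesamolin and episesamin were recovered in 19.6% of cases for genes below the median level of 102 and in 71.9% for those above it.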

Other observations

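Tests of Kupffer markers against brightness and other cell markers, and the fall imposed for the share of signal, were chosen after the result was seen. Other tests here were set beforehand. Interferon response was lower with episesamin, mean -0.24 (camera adjusted p = 0.0155; 0.546 with an estimated correlation). Of 20 genes 2 were lower, Gbp2 at -0.61 and Psmb8 at -0.46 (3 adjusted over the list alone). With sesamolin 3 of 20 were lower, Stat2 at -0.32 among them, and the list was not called (adjusted p = 0.301). Cell cycle was lower with sesamolin, mean -0.25 with 0 of 34 genes past the threshold (adjusted p = 0.0499; 0.699 with an estimated correlation). That call ended without normalization, under median scaling, by fry, with the stricter filter, with no offset, with the mean of probe sets, with the brightness covariate, without the arrays numbered 1 and without lignan-free 1, 2, 4 or 5, sesamin 2 or 5, episesamin 2, 3, 4 or 5 or sesamolin 2, 3 or 5 (adjusted p up to 0.373). Against sesamin, with 0 genes past the threshold in each list, interferon response was lower with episesamin by a mean of -0.24 (18 of 20 genes below 0, adjusted p = 0.00778; adjusted p = 0.506 with an estimated correlation). Cell cycle was lower with episesamin by -0.24 (28 of 34 genes below 0, 0.0116; adjusted p = 0.58 with an estimated correlation) and with sesamolin by -0.33 (31 of 34, 0.00052; adjusted p = 0.447 with an estimated correlation). Without episesamin replicate 1 the interferon calls ended (0.0702 against lignan-free and 0.0556 against sesamin), and the former also without lignan-free 5 or episesamin 3 (0.0511 and 0.0501) and with the brightness covariate (0.0566). Both also ended by fry (0.167 and 0.282), and that against sesamin without the arrays numbered 1 (0.0934). Both cell cycle calls against sesamin ended without sesamin replicate 1 (0.474 and 0.0622), by fry (0.428 and 0.224) and without the 6 dim arrays (0.0857 and 0.247). That with episesamin also ended without sesamin 2 (0.116), with array weights (0.088), with the actin covariate (0.0563) and without the arrays numbered 1 (0.344). Against lignan-free, AhR targets were not called (sesamin, episesamin and sesamolin: adjusted p = 0.818, 0.855 and 0.901), nor were circadian clock genes (0.819, 0.855 and 0.743), bile duct markers (0.818, 0.784 and 0.0574, the last with a mean of 0.28 and 6 of 7 genes above 0), red blood cell markers (0.28, 0.786 and 0.901) or adipocyte and exocrine pancreas markers (0.818, 0.576 and 0.961). Rora rose by 0.48 with sesamolin and Cela1 by 0.72 with episesamin, whose replicate 1 lay apart in the last list. List scores alone, by exact permutation (n = 5 per group), were lower for circadian clock with sesamolin (-0.139) and lymphocyte and neutrophil markers with episesamin (-0.28), both p = 0.0159 (0.0477 adjusted over lists). Camera called neither (0.743 and 0.0837). By permutation interferon with episesamin (adjusted p = 0.305) and cell cycle with sesamolin (0.321) did not pass. With sesamin no list passed, but the smallest possible p adjusts to 0.0595, so this test cannot decide.

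Chance was examined with 100 of the 126 splits of each 10 arrays. For genes, only the real split reached the real count against lignan-free (50, 593 and 722, highest other 5, 3 and 7) and sesamin (142 and 210, highest other 3 and 2). This argues against chance, though mixing diets may lower the other counts. For sesamolin against episesamin the real count is 0, which all 100 splits reach by construction (highest other 4), so the splits decide nothing there. For lists against lignan-free, 1 split reached 12 with sesamin (highest other 10), 4 reached 14 with episesamin (15) and 1 reached 15 with sesamolin (14). Against sesamin, 1 split reached 15 with episesamin (13) and 2 reached 14 with sesamolin (14), and 73 reached the 1 list between sesamolin and episesamin (8). Other splits called a median of 3 to 5 lists in the first 5 comparisons, so a list count from the preset correlation is weak evidence beside the calls kept with an estimated correlation.

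Kupffer cell and macrophage markers were lower with sesamolin than without lignan, by -0.54 (SE 0.10). With array brightness as a covariate the change was -0.52 (SE 0.11), which argues against brightness as the whole cause. Relative to the mean of endothelial and stellate scores the markers were lower by -0.35 with sesamolin, -0.24 with episesamin and -0.08 with sesamin. Unadjusted exact permutation p was 0.0317, 0.0476 and 0.492, and 2 of 5 sesamolin arrays lay below the lowest lignan-free array. Marker specificity was not tested, so an equal loss of Kupffer, endothelial and stellate cells stays open. Lymphocyte and neutrophil markers also fell with sesamolin, by -0.36 (SE 0.12), and Kupffer markers differed from them by -0.17 (exact permutation p = 0.159), so a shared loss of these immune cells may contribute. The 14 genes are in no other list. Fewer Kupffer cells or lower transcript levels per cell may both remain, and neither was tested.

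Median scaling left more lower than higher genes with episesamin (496 and 180) and sesamolin (457 and 178), with the median gene shifted by -0.12 (SE 0.06) with episesamin. With array brightness as a covariate the shift was -0.0477 (SE 0.0325), within 2 SE of 0, so brightness is a candidate explanation with episesamin. The covariate left -0.0371 (SE 0.0319) with sesamolin and -0.0673 (SE 0.0308, beyond 2 SE of 0) with sesamin, from -0.0885 (SE 0.0582) without it. The shifts it left overlap within SE, so no diet is set apart. The share of signal held by the raised genes grew from 1.837% to 4.092%, from which a common fall of -0.0329 in the other genes would follow. Imposing that fall on the episesamin arrays before median scaling changed the median gene's shift by 0, since the scaling removes it, so a common fall cannot give this shift. Unequal falls were not tested.

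Sesamin reached 50.6% (SD 9.14 over 5 arrays) of the episesamin and sesamolin change in genes raised by both and 23.4% (SD 8.83) in genes lowered by both. Against size-matched raised genes (37.2%), lowered genes lay -13.9 percentage points apart (SD 6.44, lower in 5 of 5 arrays). The arrays share their comparison groups, whose error the SD omits, so an equal fraction stays open. Raised genes in the fatty acid and ketone lists reached 61.4% (SD 8.84) and other raised genes 40.2% (SD 9.52), a difference not tested. A lower effective dose of sesamin in liver may contribute, and dose was not varied.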
